A study of Escherichia coli str. K-12 substr. MG1655 and Escherichia coli with 32 samples.

How the data were processed

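SeqA binding was measured on 28 arrays in 14 groups and Dam methylation on 4 arrays in 2 groups, each sample being placed in its group by its title. Per the labels' protocols, cells were crosslinked with formaldehyde, SeqA was precipitated from lysates, several precipitations were pooled, and ChIP and input DNA were labelled with Cy3 or Cy5 by random priming. ChIP DNA carried Cy5 on both AB acetate arrays, both arrays at 0 and 5 min and replicate 1 at 15, 35 and 50 min, and Cy3 on all others. For methylation, per the labels' protocols, DNA was cut with MseI, ligated to adapters, cut with DpnI or left uncut, amplified and labelled, with DpnI-cut DNA in Cy3.

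The deposited scanner files hold intensity values of 42339 features on the SeqA design and 15612 on the methylation design. Per the file headers, the authors extracted them with Agilent Feature Extraction, version 10.5.1.1 on 9 SeqA arrays and 10.7.3.1 on the other 19 and on the 4 methylation arrays, while the submitters' processing notes name 10.5.1.1 throughout. The processed signals are, per the file headers, background-subtracted, spatially detrended and scaled by a linear dye normalization factor. The deposited log10 ratio of Cy5 over Cy3 in these files served only to establish the scale and direction of the value table. The authors' value table of each design holds log2 ratios, per a comparison with the scanner ratios, running as ChIP over input or DpnI over undigested on every array but replicate 1 at 0 min, where it ran the other way (r = -0.907) and was turned. The dye labels of that array were kept because its labelled ChIP channel was dim (median signal 39.6) and its labelled input bright (30496), as in replicate 2. The labels could not be checked further, and with wrong labels the sign of that array would be inverted in both comparisons with 0 min. Its centring stays unknown. Genome positions are those printed by the deposited files for U00096, version not stated, counted from 1, and no genome sequence was used. Gene names are those of the array design, of which 3899 were current symbols and 4373 current symbols or synonyms in the RefSeq table.

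Log2(ChIP/input) was taken from the processed signals of both channels and centred on each array's median, with no loess or quantile step, since many probes can truly shift one way. Control spots and outlier spots were left out, and spots of one probe were averaged, giving 41112 probes. Probes whose log2 input, relative to the array's median, had a median below -3 over the arrays of the dnaC2 strain or over those of the other strains were left out on those arrays. Left out everywhere were 557 probes whose sequence occurs more than once on the design and 10 gene names at places over 20 kb apart. The mean over a gene's probes was its value, with a median of 8 probes per gene, 100 genes with 1 probe and 4383 genes in all. Of 11269 methylation probes overlapping a SeqA probe by 20 bases or more, 99.9% had over 95% of the shared bases equal, so positions of both designs are on one scale. Positions relative to oriC were taken from 3923472, the midpoint between mioC and mnmG. On the methylation design 15073 of 15076 probes were mapped, 6996 to fragments with 0 GATC sites, 4157 with 1, 1934 with 2 and 1986 with more, of 262 bp on average, and 5525 genes or intergenic stretches were formed. GATC density was counted on these fragments.

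All 28 SeqA arrays entered a single limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with 1 coefficient per group and a term for dye orientation, so that groups of 1 to 3 arrays share one estimate of the spread. Differences are therefore dye-adjusted and depart from differences of group means where orientations differ. The arrays with ChIP DNA in Cy5 are also the 9 extracted with version 10.5.1.1. Their slides (1, 2, 9 and 10) and scans (1 and 2) hold no array with ChIP DNA in Cy3. Their median ChIP signal was 37.0 to 89.8, but 854 on AB acetate replicate 2. The term therefore cannot tell dye from batch or signal strength, and dye-adjusted values are not corrected for dye alone. The fit had 13 residual and 6.73 prior degrees of freedom, a median residual SD of 0.41 and a median size of the dye coefficient of 0.66. The 4 methylation arrays were fitted alone. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Where no probe of a gene was well above background on any array of a group, brighter over dimmer is given as a lower bound ("at least N-fold") from the mean of the lowest signals well above background, open to dye bias. There were 374 such genes at 0 min and 5 at 5 min. A gene with a single bright probe on a single array counted as measured. Other genes at 0 min may therefore rest largely on dim probes, and their differences from 0 min are less certain. Cluster loci were tested by exact two-sided permutation of per-array means within 5 kb of the gene's midpoint, with 2 and 10 kb as other windows. Bins of 5 kb were fitted like genes, and windows of 100 kb in steps of 25 kb gave the profiles. The highest window was the planned measure of the front, and the edge was defined after the profiles were seen.

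The groups, tests, lists, distance bands and naming rule were fixed before the data were examined. Lists held genes around oriC, the dnaA operon region, replication, repair and topology, nucleotide synthesis, ribosomal proteins, other highly transcribed genes, rRNA genes, flagella and chemotaxis, surface polysaccharide, cryptic prophages and the neighbours of the terminus. They and the bands from oriC were tested per comparison with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a set's genes move, on balance, one way and compares them with no other genes. Of 179 tests 93 passed at the preset correlation, 5 with an estimated one and 31 by fry. Named are, per comparison, the first 10 genes higher and 10 lower by size among those past the threshold whose arrays do not overlap, none within 25 kb of another, a fixed set of landmark genes, the 2 members of each list with the smallest adjusted p in each direction, and the 3 bins with the smallest adjusted p. So every array of one group lies on one side of the other group at each gene of the first kind. The genes asnA, atpG and others near oriC come from the lists.

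Slides (numbered 1 to 12) and scans (1 to 8) were read from the headers, and where a batch holds several groups the values with it as a block and within it are given. Replicate numbers on the methylation arrays mark crosslinking, per the labels' protocols, so they pair the samples (correlation of deviations 0.676). On the SeqA arrays some equal numbers share a slide, as do some unequal ones, and the labels give no other tie. The calculations were tested on simulated data. Of 200 genes changed by a log2 of 1, 2 or 3, the share recovered was 7.58%, 68.8% and 94.7% for 5 against 0 min and 1.75%, 51.3% and 83.1% for the Dam comparison. For 35 against 15 min it was 14.1%, 74.0% and 98.2%, and for methylation 0%, 11.6% and 68.3%. Edges of 60 simulated profiles, each a flat level with a sharp drop and independent noise, were placed within 25 kb. Real profiles are not of this form, so this does not give their error. Alternatives covered dye, background, scaling, dim probes, the summary per gene, the value table, the samples in the fit, pairing, slide, scan, array weights and leaving out arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. A SeqA4 mutant that the series names is not analysed here.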

Results

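SeqA, an Escherichia coli protein that binds GATC sites methylated on the old strand alone, as they are just after a replication fork has passed, was mapped on MG1655 and its derivatives with 28 tiling arrays. Each array set DNA recovered with an antibody against SeqA beside input DNA of the same culture, and 4 arrays of another design measured Dam methylation. In the dnaC2 strain, whose helicase loader fails at high temperature, cells were grown at 30 °C, held at 39 °C for 70 min so that rounds of replication finished without new initiations, and returned to 30 °C. Cells were taken at 0 min (2 arrays), 5 min (2), 15 min (3), 16 min (2), 17 min (2), 35 min (2) and 50 min (2) after the return, in AB glucose CAA medium. A further 3 arrays held dnaC2 cells 15 min after the return that the titles place in LB, 2 of them from a strain overproducing Dam, the adenine methyltransferase of GATC. Unsynchronised cells comprised the wild type in AB acetate (2 arrays) and 4 strains in LB with glucose, each carrying an inserted cluster of GATC sites at tnaA, hisA, srlA or the terminus (2 arrays each). Levels are log2(ChIP/input) with each array's median at 0, differences between groups are on the same log2 scale, and errors of levels are SD over arrays. The arrays' number limits the precision.

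Signal over background differed between the samples. The median ChIP signal was 39.6 and 38.3 on the arrays at 0 min, where 43.1% and 40.1% of probes were well above background, and 37.0 on replicate 2 at 5 min, with 38.5% well above. Replicates 1 at 5, 15, 35 and 50 min had medians of 81.5, 72.1, 54.1 and 42.5 and shares of 96.8%, 94.5%, 88.6% and 76.6%, and replicate 2 at 17 min had 115 and 91.4%. Input DNA was well above background at 99.3% or more of probes on every array. It was saturated at 17.8% of probes on replicate 1 at 15 min, 11.2% on replicate 2 of tnaA and 10.1% on replicate 1 at 35 min. On the other SeqA arrays this share was at most 4.25%. On the methylation arrays 11.4% to 14.5% of probes were saturated in DpnI-cut DNA. Replicate 1 of the Dam overproducer had 10196 outlier spots, leaving 30759 of 41112 probes. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Across probes, which are not independent, replicates correlated at r = 0.25 in AB acetate, 0.38 at 0 min, 0.33 at 5 min, 0.48 at 35 min and 0.59 at 50 min. At 15 min r was 0.33 and 0.36 between replicate 1 and the others and 0.92 between these, and the remaining groups of 2 SeqA arrays had r from 0.67 to 0.91.

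The description fields of 6 arrays raise doubts about what they hold, and all 6 were kept under their titles. Both AB acetate arrays and replicate 1 of hisA are said to come from an earlier method with high background, and replicate 2 at 0 min from a shortened RNA digestion, also with high background. Replicate 2 of hisA is described as a wild-type control, and replicate 1 of srlA as a test of crosslinking that involved no ChIP. Within 5 kb of its own locus replicate 2 of hisA was at 0.72, where the other strains had -0.40 to 0.02, and replicate 1 of srlA at 1.88, where the other strains had 0.28 to 0.77. These values, looked up after the results were seen, argue against a strain without the insertion and against DNA without ChIP, and they go with the titles.

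Release from the block was followed within 5 min by SeqA recovery next to oriC, the question being where newly replicated DNA first carries the protein. At mioC, a flavodoxin gene bordering oriC (3924000 to 3924432), the level was 5.46 ± 1.81 at 5 min and -0.28 ± 0.01 at 0 min (n = 2 each), a difference of 5.74 (SE 0.80, adjusted p = 9.3e-04, limma). On the other side of oriC, mnmG, a tRNA modification gene, was higher by 4.95 (SE 0.62, adjusted p = 5.4e-04). The initiator gene dnaA (3880368 to 3881733), 42.4 kb from oriC, stood at 3.40 ± 1.47 against -0.06 ± 0.13, a difference of 3.47 (SE 0.55, adjusted p = 0.00184). The difference was 2.44 at gpp, for a guanosine pentaphosphatase, 38 kb away on the other arm, 1.92 at yigB and 1.97 at mutM, a DNA repair glycosylase gene, the latter 115 kb from oriC (adjusted p 0.0102, 0.022 and 0.0264). It was 2.12 at ilvN, for acetohydroxyacid synthase, 74.5 kb away (adjusted p = 0.0333). Away from this part of the chromosome, lpp and tus, 2 genes near the terminus, differed by 0.16 each, and seqA itself by -0.02.

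Among 4331 genes tested, 47 were higher at 5 min and 0 lower, and 211 had an unadjusted p under 0.05. The arrays of both groups did not overlap at any of the 47. Chance alone separates 2 arrays from 2 at 33.3% of unselected genes. Since the 47 were selected by p on these same arrays, their separation is no independent support. The same holds for the arrays counted as apart in the later comparisons. Of the 21 genes around oriC fixed as a list, 19 were higher over all genes and 21 when adjusted over the list alone. Their median difference was 3.27 (adjusted p = 3.2e-83 by camera, adjusted p = 0.00252 with an estimated correlation). The list held asnA, asparagine synthetase, at 3.83 and the ATP synthase gene atpG at 3.77. The ATP synthase genes atpC, atpF and atpI, not well above background at 0 min, were at least 6.88-fold, 5.67-fold and 3.06-fold higher. Of 7 measured genes of the dnaA operon region, 4 were higher over all genes and 7 when adjusted over the list alone, with a median of 2.24 (camera adjusted p = 1.5e-22, adjusted p = 0.00401 with an estimated correlation), including mnmE at 2.36 (adjusted p = 0.0058) and rnpA at least 1.79-fold. In that region gyrB, a DNA gyrase subunit gene, differed by 0.96 and tnaA by 1.00, neither passing (adjusted p 0.388 and 0.56). The genes within 100 kb of oriC had a median of 1.27, with 45 of 181 higher and 124 when adjusted over the list alone (camera adjusted p = 2.7e-153, adjusted p = 0.00401 with an estimated correlation). From 100 to 250 kb the median was 0.33 (adjusted p = 0.736 with an estimated correlation) and every band from 250 kb on had a median from 0.01 to 0.08. Replication and repair genes (median 0.30, 1 of 42 higher, 3 adjusted over the list alone), nucleotide synthesis genes (0.20, with pyrE, near oriC, higher by 1.82), ribosomal protein genes (0.41) and rRNA genes (0.23, falling to -0.36 with another scaling) did not pass with an estimated correlation. Nor did other highly transcribed genes (0.13), flagella and chemotaxis (-0.04), surface polysaccharide (0.19), cryptic prophage (-0.08) or terminus genes (0.18).

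Both 5 min arrays share a slide with a 0 min array, and slide or scan as a block left the medians of the oriC list and of the 100 kb band at 3.27 and 1.27. This was fixed by the layout. Both times are spread alike over the same slides and scans, so a block cancels from the difference and cannot test for batch. On the slide with replicates 1 these medians were 4.10 and 2.18, and on that with replicates 2 they were 2.03 and 0.87. The count was 0 after normexp background correction and 0 in a fit of these 4 arrays alone, and it was 11 and 13 without replicate 1 and 2 at 0 min, and 1 and 130 without replicate 1 and 2 at 5 min.

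**Figure D1:**
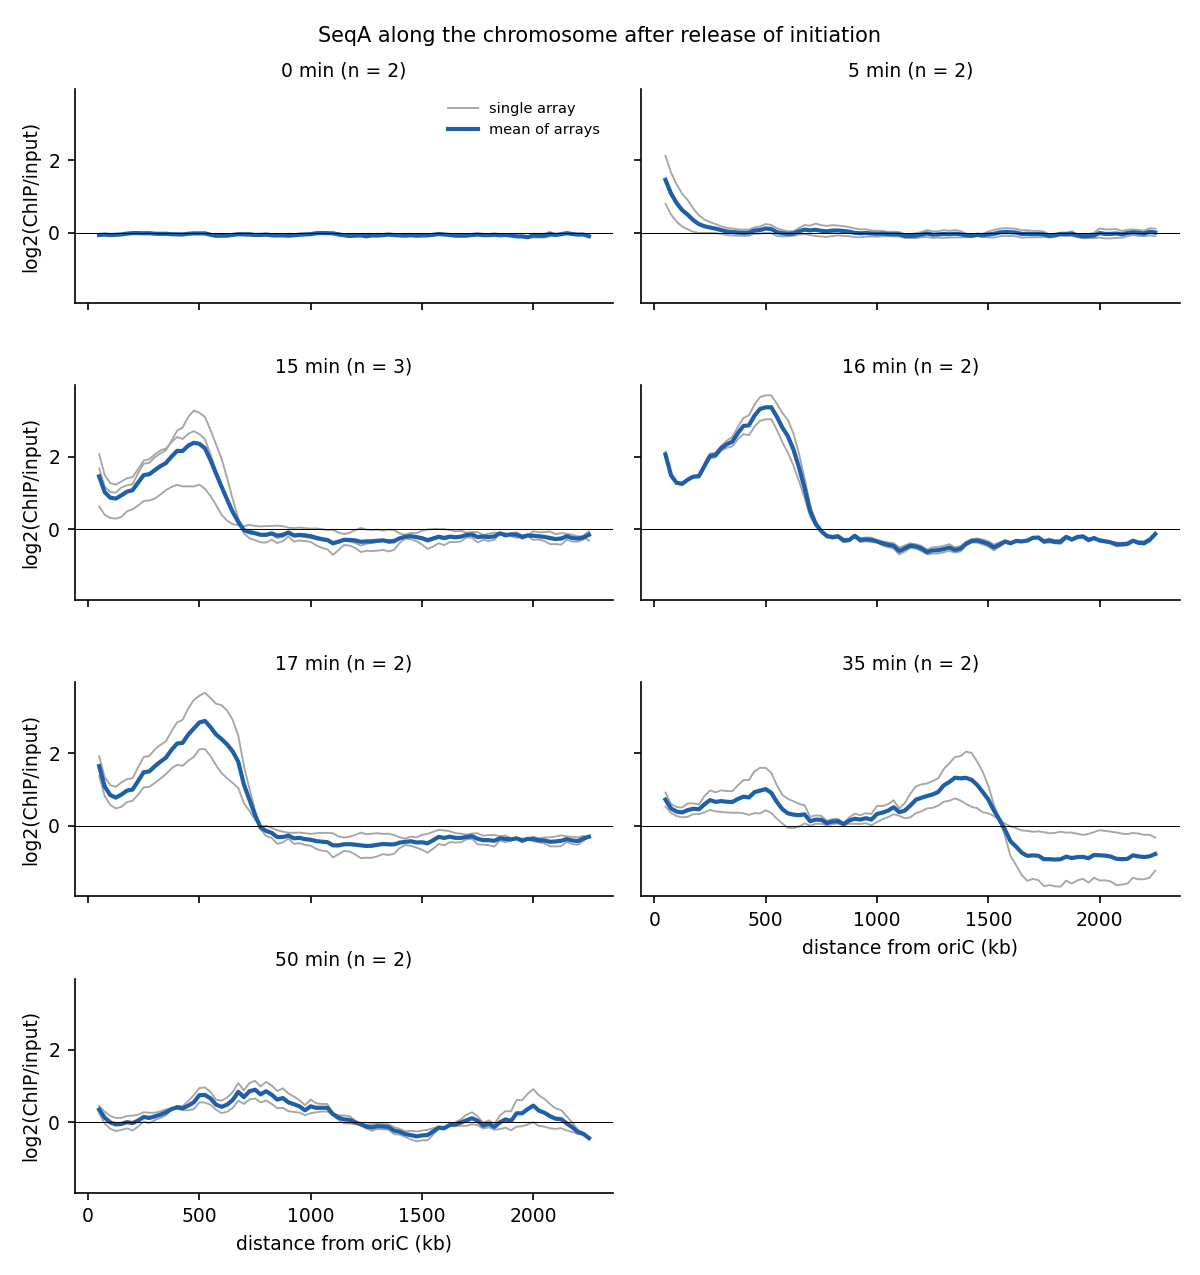
Mean log2(ChIP/input) in windows of 100 kb (vertical axis) against distance from oriC in kb (horizontal axis) for the 0, 5, 15, 16, 17, 35 and 50 min groups, with grey lines for single arrays and blue lines for group means. The outer edge of enrichment lay at 93.8 kb at 5 min and 1506 kb at 35 min, and the 0 min profiles were flat.

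At 15 min differences from 0 min extended outward on both arms, while the greatest remained next to oriC, at mioC, with a level of 6.41 ± 1.72 (n = 3) and a difference of 5.60 (SE 0.84, adjusted p = 2.2e-04), and at mnmG (4.29). Among genes none of which lies within 25 kb of another, the next 3 lay 299 to 494 kb from oriC. They were phnP, of phosphonate use (4.23, SE 0.42, adjusted p = 5.1e-06, 389 kb clockwise), yhhJ (4.14, SE 0.41, adjusted p = 5.1e-06, 299 kb counterclockwise) and ulaG, of ascorbate use (4.25, SE 0.50, adjusted p = 1.9e-05, 494 kb clockwise). Smaller differences were found at psiE (3.51), php (3.48), the DNA adenine methyltransferase homologue yhdJ (3.37) and zntR, a zinc efflux regulator (3.34), with adjusted p from 5.1e-06 to 0.0027, while yjgA, 532 kb away and dim at 0 min, was at least 13.5-fold higher. At dnaA the level was 4.37 ± 0.77, higher by 3.73 (SE 0.58, adjusted p = 2.9e-04). The dam gene was at 1.58 against -0.37 and rpoB at 2.41 against -0.13, but their dye-adjusted differences of 1.28 and 1.61 did not pass (adjusted p 0.221 and 0.094). Lower at 15 min were yqgC by 1.08 (difference -1.08, SE 0.31, adjusted p = 0.0365) and pheL and ylcG, for which no fold can be given because they were not well above background.

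The count was 310 higher and 3 lower of 4331 (782 at an unadjusted p under 0.05). Arrays did not overlap for 308 and 3 of them (20% by chance at unselected genes for 2 against 3). Genes 250 to 500 kb from oriC had a median of 1.37, with 196 of 470 higher and 337 when adjusted over the list alone (camera adjusted p = 9.6e-72, adjusted p = 0.187 with an estimated correlation, fry adjusted p = 0.00892). Within 100 kb the median was 0.90 with 29 higher (56 adjusted over the list alone), from 100 to 250 kb 0.77 with 24 higher (29), and from 500 to 750 kb 0.40 with 58 higher (71). The camera calls of these bands were lost with an estimated correlation, at adjusted p 0.432, 0.432 and 0.661. Beyond, medians were -0.16 at 750 to 1000 kb, -0.32 at 1000 to 1500 kb and 0.05 farther out. The oriC list kept a median of 2.43 (14 higher, 21 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation), and the dnaA operon region 1.50 (3 higher, 6 adjusted over the list alone). Nucleotide synthesis genes were higher at 5 of 36 (6 adjusted over the list alone), among them pyrI of pyrimidine synthesis (3.17) and nrdD, the anaerobic ribonucleotide reductase (2.23), with a list median of 0.25 that reached -0.04 under another scaling. Replication and repair genes were higher at 5 (6 adjusted over the list alone), among them uvrA, of excision repair (2.81, adjusted p = 6.7e-05), and mutL, of mismatch repair (2.50, adjusted p = 1.1e-04). Their median of 0.34 turned to -0.20 after normexp correction. Of 51 ribosomal protein genes 6 were higher (9 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.661 with an estimated correlation), led by rpsJ and rplP at no less than 4.92-fold and 7.98-fold. The rRNA gene list had a median of 1.34 and 1 gene higher, rrfB at 2.61 (1 adjusted over the list alone), and its copies are near identical. Other highly transcribed genes were higher at 4 (5 adjusted over the list alone), including the chaperonin groL (1.85) and the RNA polymerase gene rpoC (1.71), around a list median of 0.12. No gene passed among flagella (-0.04), surface polysaccharide (0.32), terminus (0.09) and prophage genes (-0.13), and camera called none of these 4 lists.

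With slide or scan as a block the 250 to 500 kb median was 1.43 or 1.54, the oriC median 2.23 or 2.32 and the 100 kb median 0.77 or 0.84. On the slide holding an array of both times they were 1.1, 1.69 and 0.69. The count fell to 45 after normexp correction and 147 with slide as a fixed block, and it was 133 and 124 without replicate 1 and 2 at 0 min and 573 without replicate 1 at 15 min.

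The 16 and 17 min groups give the progress of SeqA over 1 or 2 min more. At 16 min the levels were 7.45 at mioC, 5.33 ± 0.12 at dnaA and 2.36 at dam, and no gene differed from 15 min (0 of 4331 by limma, 221 at an unadjusted p under 0.05). The genes with the smallest adjusted p of their lists, holC and dnaC of replication and pyrB and nrdD of nucleotide synthesis, differed by 1.39, 1.15, 0.75 and 0.90 (adjusted p from 0.2 to 0.74). The band from 500 to 750 kb had a median of 0.83, with 59 genes higher when adjusted over the list alone (camera adjusted p = 4.8e-68, adjusted p = 0.104 with an estimated correlation). Slide or scan as a block gave 0.86 or 0.89 for this band, and it was 0.85 and 0.64 on the slides that hold both times. One replication gene passed when adjusted over the list alone and 0 in every other functional list. Without replicate 1 at 15 min 1 gene passed.

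At 17 min genes 602 to 712 kb from oriC were higher than at 15 min. They included yqjK (2.69 ± 0.58 against -0.21 ± 0.38, difference 2.87, SE 0.33, adjusted p = 1.2e-04), yjiN (2.42) and rpoD, the housekeeping sigma factor (2.33, adjusted p = 0.0275). In this zone were also agaS (2.32), the serine chemoreceptor gene tsr (2.11), sgcE (1.68) and the lipoate ligase gene lplA (1.56, adjusted p = 0.0291). Of replication genes, holD, a clamp loader subunit, differed by 1.93 and dnaG, the primase, by 1.90 (adjusted p 0.0092 and 0.027). In all 93 genes were higher and 2 lower (354 at an unadjusted p under 0.05), with arrays apart at 92 and 1 (20% by chance at unselected genes). Of the 2 lower, hha was measured on only 1 of the 2 arrays at 17 min, so its call has no spread of its own there and does not establish a decrease, and at yfjT, named after its value was seen, the arrays overlapped. Every one of the 93 belonged to the band from 500 to 750 kb, whose median was 0.85, with 182 higher when adjusted over the list alone (camera adjusted p = 5.4e-101, adjusted p = 0.0243 with an estimated correlation). Replication genes were higher at 3 (4 adjusted over the list alone), with a median of 0.07 and adjusted p = 0.979 with an estimated correlation. Surface polysaccharide and prophage lists had medians of -0.78 and -0.62 (camera adjusted p 0.0054 and 0.0013, adjusted p = 0.979 with an estimated correlation for both), with 0 genes past the threshold. With slide or scan as a block the band's median was 1.01 or 0.91, and on the shared slide and the shared scan it was 0.32 and 1.41. The count fell to 1 after normexp, with array weights and without replicate 1 at 17 min, to 0 in a fit of the 5 arrays alone, to 42 and 46 without replicates 2 and 3 at 15 min and to 9 with slide as a fixed block, and was 206 without replicate 2 at 17 min.

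At 35 min SeqA was higher than at 15 min mainly at genes 1000 to 1500 kb from oriC, and the 10 leading genes on the lower side lay between 15.5 and 556 kb. At acrA, of multidrug efflux, 1200 kb clockwise, the level was 3.03 ± 1.21 (n = 2) against -0.46 ± 0.20 at 15 min (n = 3), a dye-adjusted difference of 3.66 (SE 0.34, adjusted p = 5e-06). At hda, whose product inactivates DnaA, 1307 kb counterclockwise, it was also 3.66 (SE 0.47, adjusted p = 3.3e-05). The esterase gene ybfF, rlpB, thiL of thiamine synthesis, iscX and ddlA, for a cell wall ligase, were higher by 3.34, 3.33, 3.32, 3.11 and 3.06, and eutH, crr of sugar transport and prpB by 3.02, 3.01 and 2.93. The seqA gene itself rose from -0.10 ± 0.33 to 2.02 ± 1.51 (difference 2.21, SE 0.40, adjusted p = 6.1e-04). Lower than at 15 min was rnr, for RNase R, 482 kb clockwise (0.13 ± 0.11 against 2.01 ± 0.63, difference -1.81, SE 0.31, adjusted p = 3.9e-04). The other leading genes on this side were phnJ (-1.76), frdA of fumarate reductase (-1.75), rtcR (-1.64), the phosphate transporter gene pstC (-1.63), nanK (-1.62), nrfC (-1.61), fumB (-1.60), ytfN (-1.59) and yheS (-1.57). At mioC and dnaA the differences were -0.73 and -0.36 (adjusted p 0.423 and 0.565), and both remained at 5.40 and 3.84 ± 0.50.

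In numbers, 591 genes were higher and 345 lower (1785 at an unadjusted p under 0.05), arrays being apart at 494 and 243 (20% by chance at unselected genes). With only probes well above background 239 were higher and 276 lower. The median of all genes was -0.48 in this comparison, -0.30 when arrays were scaled to one median absolute deviation and -0.60 over well measured probes. Relative to -0.48, the 1000 to 1500 kb band lay 1.56 higher and the 750 to 1000 kb band 0.64 higher, while the 250 to 500 kb band, the oriC list, the flagella list and the band beyond 1500 kb lay at -0.59, -0.53, -0.28 and -0.19. Before this subtraction the 1000 to 1500 kb median was 1.07, with 479 genes higher and 550 when adjusted over the list alone (camera adjusted p = 2.1e-107, adjusted p = 0.00614 with an estimated correlation). The 250 to 500 kb median was -1.08, with 213 lower (280 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation, fry adjusted p = 0.0169). From 500 to 750 kb 8 were higher and 73 lower (7 and 65 adjusted over the list alone), and from 750 to 1000 kb 63 were higher (47). Beyond 1500 kb the median was -0.67, with 33 higher and 45 lower (18 and 0 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation, fry adjusted p = 0.0486). Mean levels there were -0.20 ± 0.08 at 15 min and -0.71 ± 0.78 at 35 min, and the median turned to 0.067 without replicate 2 at 35 min and was -1.27 without replicate 1, so its direction rests on 1 array. Replication and repair genes went both ways, 7 higher and 4 lower (13 and 7 adjusted over the list alone), with a median of -0.25 and a mean of 0.06. In that list holA, a clamp loader gene, was at 2.29, and mutL and uvrA were at -1.66 and -1.35. Of nucleotide synthesis genes 6 were higher, with purF, the first enzyme of purine synthesis, at 2.51 and ndk at 1.64, and 4 lower, with purA at -1.64 and nrdD at -1.22 (6 and 5 adjusted over the list alone). That list had a median of -0.28 and a mean of 0.03. Other highly transcribed genes were higher at 3 and lower at 2 in both adjustments, led by hupB (1.75), fbaA (1.24), groS (-1.37) and groL (-1.37), with a median of -0.51 that became 0.41 under another scaling. The ribosomal protein list had rpsP at 1.62 and rpsJ at -1.22 past the threshold, with a median of -0.65. The oriC list had 4 lower, with rbsC at -1.40 and atpC at -1.52, flagella 1, flgH (-1.21), terminus genes 3, with marC (-0.97) and dcp (-0.85), and prophages 1, dicF (-1.33). Adjusted over the list alone, 0 passed in the oriC, flagella and terminus lists and 1 among prophages. The medians of these 4 lists were -1.02, -0.76, -0.65 and -0.57, with adjusted p = 0.833 with an estimated correlation in the first 3. The rRNA and surface polysaccharide lists, with medians of -0.94 and -0.56, had 0 past the threshold.

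Slide or scan as a block gave 0.98 or 1.11 for the 1000 to 1500 kb band and -1.06 or -1.17 for the 250 to 500 kb band. On the shared slide these were 0.49 and -0.70, and on the shared scan 1.76 and -1.31. The count was 1523 without replicate 1 at 15 min, 568 and 596 without replicates 2 and 3, 2034 and 43 without replicate 1 and 2 at 35 min, and 158 with slide as a fixed block.

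At 50 min, against 35 min, SeqA stood lower between 1000 and 1500 kb and, in the fit, higher toward the terminus. Beyond 1500 kb the mean levels of replicates 1 and 2 were -0.16 and -1.26 at 35 min. At 50 min they were -0.19 and 0.10. Replicates 1 thus showed no rise of this band, and its rise rests on replicates 2. Around 1956 kb from oriC cheR, of chemotaxis, had 2.42 ± 0.89 against -0.44 ± 0.52 (n = 2 each), a difference of 2.86 (SE 0.40, adjusted p = 0.0025). The nitrate response regulator gene narL stood at 2.34 ± 1.37 against -0.59 ± 0.35 (difference 2.92, SE 0.54, adjusted p = 0.0048). Also higher were pyrD of pyrimidine synthesis (2.87), ynjC (2.62), the transcription-repair gene mfd (2.56), flgM, an anti-sigma factor gene (2.48), yeaK (2.41), the trehalase gene treA (2.36), ydiR (2.31) and hyaB of a hydrogenase (2.21). The genes glnS, for glutaminyl-tRNA synthetase (-2.38, SE 0.41, adjusted p = 0.0045), dacA of cell wall synthesis (-2.63), argT (-2.33), ybdF (-2.32) and sdhD of succinate dehydrogenase (-2.17) were lower. So were valX, a tRNA gene with 1 probe (-3.04), rpsH (-2.06), acrR (-2.06) and talA (-2.04), and seqA fell back from 2.02 to -0.06 (difference -2.09, SE 0.43, adjusted p = 0.0056). At mioC and dnaA the differences were -0.18 and -0.26. The prophage gene rzpR passed too (-1.98), but it lies in a stretch where the dnaC2 arrays had next to no input DNA, so its value cannot be read as SeqA at that gene.

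Of 4331 genes 358 were higher and 368 lower (1362 at an unadjusted p under 0.05), with arrays apart at 340 and 340 (33.3% by chance at unselected genes). With only well measured probes 131 were higher and 64 lower. The median of all genes was -0.02, and 0.10 with only well measured probes. Of 38 flagella and chemotaxis genes 25 were higher and 36 when adjusted over the list alone. Their median was 1.42, or 1.44 relative to all genes (camera adjusted p = 1.4e-17, adjusted p = 0.329 with an estimated correlation, fry adjusted p = 0.00835), with flhA at 2.30. These genes lie mostly beyond 1500 kb, where the band's median was 0.68, or 0.70 relative to all genes, with 314 higher and 36 lower (394 and 40 adjusted over the list alone, adjusted p = 0.202 with an estimated correlation). Between replicates 1 the mean level of this band did not rise (-0.16 at 35 min, -0.19 at 50 min). The 1000 to 1500 kb band had -0.95, or -0.93 relative to all genes, with 319 lower (407 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). From 750 to 1000 kb 30 were higher (0 adjusted over the list alone). Replication genes were higher at 7 and lower at 2 in both adjustments, with the topoisomerase gene topB at 1.93, mukB of chromosome organisation at 1.70 and holA at -1.89. Their median of 0.07 became -0.07 under another scaling. Nucleotide synthesis genes were higher at 3, with pyrF (1.50), and lower at 5, with purF (-1.79) and purC (-1.73) (3 and 6 adjusted over the list alone). Other highly transcribed genes were higher at 1, ompA (1.45), and lower at 3 in both adjustments, with ahpC at -1.25 and cspE at -1.76. Ribosomal protein genes had a median of -1.07 (adjusted p = 0.81 with an estimated correlation) and 3 lower, with rpsK at -1.81 (0 adjusted over the list alone). Of terminus genes 1 was higher, fumA (1.27), and of prophages 1 lower, ybcQ (-1.28), with medians of 0.07 and -0.19. The rRNA and oriC lists had medians of -0.92 and -0.61 with 0 past the threshold.

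With slide or scan as a block the medians were -0.94 or -0.93 for 1000 to 1500 kb, 0.84 or 0.82 beyond 1500 kb and 1.70 or 1.69 for flagella. On the shared slide, which holds replicates 2 only, they were -1.30, 1.36 and 2.34. The count was 0 after normexp correction, with array weights, or without replicate 2 at 35 or at 50 min, 1418 and 1175 without replicate 1 at these times, and 15 in a fit of these 4 arrays alone.

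The outer edge of SeqA enrichment, the farthest 100 kb window at or above midway between the highest window and the median beyond 1800 kb, was at 93.8 ± 26.5 kb at 5 min, 592 ± 19.1 kb at 15 min, 644 ± 8.84 kb at 16 min, 669 ± 26.5 kb at 17 min and 1506 ± 44.2 kb at 35 min. It was at 994 ± 115 kb at 50 min. The window with the highest level was centred at 50 kb at 5 min, 463 ± 12.5 kb at 15 min, 500 ± 17.7 kb at 16 min, 519 ± 8.84 kb at 17 min, 1100 ± 442 kb at 35 min and 619 ± 8.84 kb at 50 min. After normexp correction the edge moved to 650 ± 796 kb at 5 min and 1188 ± 159 kb at 50 min. The mean level of genes within 100 kb of oriC was -0.06 ± 0.00 at 0 min, 1.46 ± 0.93 at 5 min, 1.46 ± 0.75 at 15 min, 2.07 ± 0.10 at 16 min, 1.65 ± 0.39 at 17 min, 0.72 ± 0.28 at 35 min and 0.35 ± 0.15 at 50 min. The level of genes from 500 to 750 kb was 0.39 ± 0.45 at 35 min and 0.65 ± 0.27 at 50 min.

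**Figure D2:**
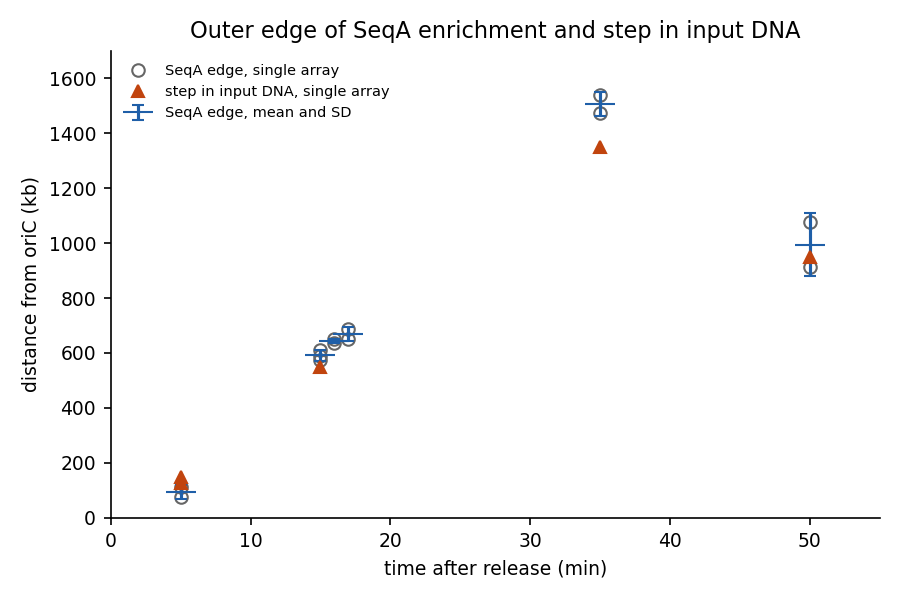
Distance from oriC in kb (vertical axis) of the outer SeqA edge against time after release in min (horizontal axis), with open circles for single arrays, bars for group means with SD and triangles for the step in input DNA on the 5 arrays that share a slide with a 0 min array. The mean edge was at 592 kb at 15 min and 669 kb at 17 min, and the steps lay within 125 kb of the edges of their arrays.

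Whether extra Dam changes SeqA behind the forks was asked at 15 min with 2 arrays of the overproducer and 1 of its parent, all titled LB although the protocol field names AB glucose CAA. At mioC the overproducer was at 6.22 ± 0.25 and the parent at 7.37, a difference of -1.15 (adjusted p = 0.53), and at dnaA it was at 4.24 ± 0.73 against 5.86, a difference of -1.62 (adjusted p = 0.176). The ATP synthase genes atpI and atpF, near oriC, differed by -2.86 and -2.63, dnaB, the replicative helicase, by -1.64, groS by -2.05 and the lipopolysaccharide gene rfaF by -1.64 (adjusted p = 0.051 for each). Next came gyrB (-1.47), pyrE (-1.60), dut, the dUTPase (-1.56), ydeP (-1.29), dnaN, the sliding clamp (-1.52), and tnaA (-1.52), at adjusted p from 0.055 to 0.085. On the other side acpP, the acyl carrier protein gene, differed by 1.92 and rplS by 1.45. The difference at dam was -1.29. Input DNA of dam exceeded that of its neighbours by 0.49 and 0.79 in the overproducer and by -0.12 in the parent. The SeqA ratio at dam was 1.3 and 2.8 in the overproducer and 3.4 in the parent. Its neighbours had 2.2 and 2.4 against 3.6, so a fall particular to dam was not shown. Whether the extra input DNA lowered the ratio at dam was not tested. No gene passed (0 of 4331 by limma, 857 at an unadjusted p under 0.05), and 123 passed with only well measured probes.

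Genes within 100 kb of oriC had a median of -1.53, or -1.50 relative to all genes, whose median was -0.03 and, over well measured probes, -0.28. When adjusted over the list alone 142 were lower (camera adjusted p = 1.3e-36, adjusted p = 0.254 with an estimated correlation, fry adjusted p = 0.0275). The medians were -1.34 from 100 to 250 kb (182 lower adjusted over the list alone), -1.20 from 250 to 500 kb (169) and -0.66 from 500 to 750 kb, and that from 1000 to 1500 kb was 0.52. The oriC list had -2.36 (16 lower adjusted over the list alone, adjusted p = 0.318 with an estimated correlation, fry adjusted p = 0.0362) and the dnaA operon region -1.47 (7 lower adjusted over the list alone). Scaled to one median absolute deviation, the oriC list, the dnaA operon region and the 250 to 500 and 500 to 750 kb bands changed sign, to 0.61, 0.61, 0.47 and 0.17, and the 100 kb band was at -0.12. Replication genes had a median of -0.38 (6 lower adjusted over the list alone) and ribosomal protein genes -0.74, and both changed sign under that scaling, to 0.12 and 1.04. Surface polysaccharide genes stood at -0.71 (2 lower adjusted over the list alone) and terminus genes at -0.55 (1 lower, adjusted p = 0.521 with an estimated correlation). With slide or scan as a block the 100 kb, 250 to 500 kb and oriC medians were -1.51, -1.08 and -1.92, while the ribosomal protein list turned to 0.14 and the rRNA list went from -0.50 to 0.24 (0.87 under that scaling), and on the slide shared with the parent -1.49, -1.01 and -1.88. The outer edge was at 600 ± 0 kb in the overproducer and 600 kb in the parent. The count was 22 with slide and 24 with scan as a fixed block, 604 with array weights, and 1 without replicate 1 of the overproducer. The parent is 1 array, assumed to vary like the other groups.

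The LB parent was also set against the 3 arrays of dnaC2 cells in AB glucose CAA at 15 min, a comparison of media if the titles hold. LB is 1 array with no spread of its own, so every p here borrows the spread of other groups and does not by itself establish a difference between media. Near oriC the LB array was higher at pstB, of phosphate transport (2.62, SE 0.63, adjusted p = 0.0187), rbsK, ribokinase (2.37, SE 0.48, adjusted p = 0.0146), rffG (2.32), dgoR (2.04), pldB (2.09), rpoZ, the omega subunit of RNA polymerase (2.52), and rfaF (2.37, SE 0.39, adjusted p = 0.0086). Farther out were yhfG (2.03) and yhbO (2.11), and 2265 kb away fdnH, of formate dehydrogenase, at 2.99 against 0.31 ± 0.26 (difference 2.76, SE 0.47, adjusted p = 0.0105). Lower in LB were yfbO (-2.66, SE 0.72, adjusted p = 0.0281), ykgH (-2.02), yadK (-1.86), yfjU (-1.77), the regulator gene evgA (-1.75), ybcY (-1.64), ygbF (-1.61), ygeQ (-1.57), essQ (-1.57) and gloB, for a glyoxalase (-1.50). At mioC, dnaA and tnaA the differences were 0.42, 1.13 and 1.35 (adjusted p 0.836, 0.296 and 0.0661). In all 366 genes were higher and 26 lower (1093 at an unadjusted p under 0.05), with the arrays apart at 366 and 25, where chance gives 50% for 1 against 3. These counts did not hold, falling to 0 with arrays scaled to one median absolute deviation and to 2 with slide and 7 with scan as a fixed block.

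The median of all genes was 0.15, and 0.36 with only well measured probes. Relative to 0.15, the bands within 100 kb, from 100 to 250 kb and from 250 to 500 kb lay at 1.47, 1.12 and 0.91, the oriC list at 1.65 and cryptic prophages at -1.22. Over all genes 80, 106 and 79 genes of these bands were higher, and 134, 162 and 173 when adjusted over the list alone (adjusted p 0.338, 0.338 and 0.412 with an estimated correlation). From 500 to 750 kb 40 were higher (39 adjusted over the list alone), and from 1000 to 1500 kb 18 were lower (0). The dnaA operon region was higher at 5 (6 adjusted over the list alone), including gyrB (1.64, adjusted p = 0.0192) and mnmE (2.04), and the oriC list at 7 (14), including atpI (2.56) and rbsB (2.30). Terminus genes were higher at 7 (10 adjusted over the list alone), with lsrA of autoinducer uptake at 1.84 and ydeP at 1.46, around a median of 0.86 (adjusted p = 0.412 with an estimated correlation, fry adjusted p = 0.0114). Replication genes were higher at 6 in both adjustments, including dnaB (1.80) and rep (2.00), nucleotide synthesis genes at 4 (7), including pyrE (2.37) and dut (1.90), and ribosomal protein genes at 4 (2), including rpsJ (1.87) and rplP (1.94). Medians were 0.78, 0.29 and 1.00, the nucleotide list turning to -0.17 with only well measured probes and -0.04 after normexp. Surface polysaccharide genes had a median of -0.81, turning to 0.17 under another scaling, with 2 higher (3 adjusted over the list alone), including waaA (1.48). Other highly transcribed genes had 0.05 and 1 higher, groS (1.65), and rRNA genes 0.78 with 0.

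The groups share no slide or scan, so no value within a batch can be had. With slide or scan as a block, which ties them through other groups, the 100 kb median was 1.84 or 1.87, the 250 to 500 kb median 0.69 or 0.78, prophages -2.08 or -1.88 and terminus genes 1.20 or 1.25, while the ribosomal protein list turned to -1.99 or -1.75, the rRNA list to -3.79 or -3.07, other highly transcribed genes to -1.01 or -0.98 and the 750 to 1000 kb band from -0.18 to 0.30 or 0.16. Surface polysaccharide genes stood at -3.84 or -3.81 with these blocks. The count was also 0 without the arrays that a description sets apart, and it was 229 and 221 without replicates 1 and 2 in AB glucose CAA.

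**Figure D3:**
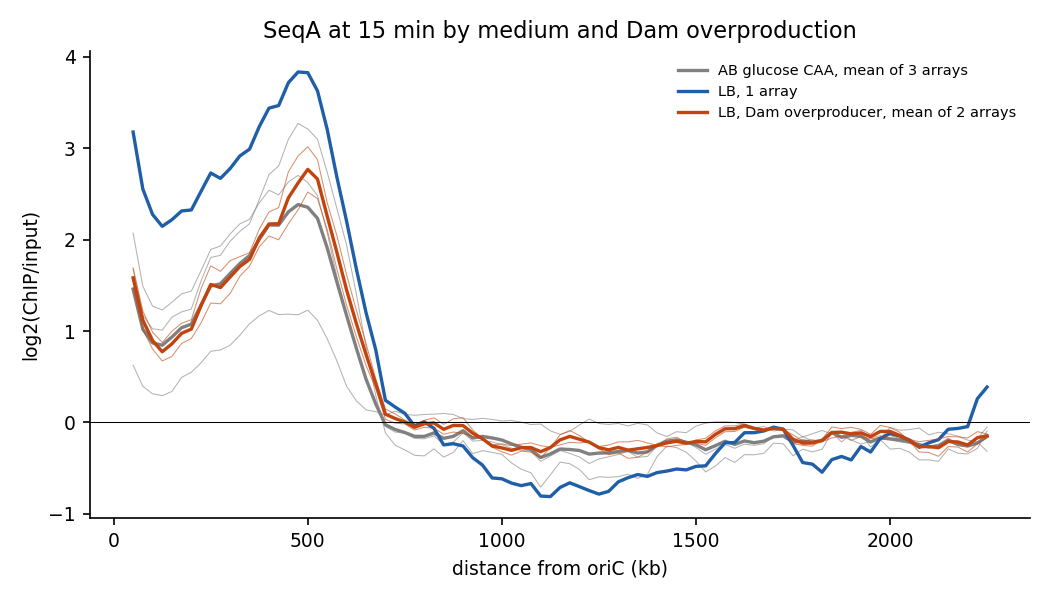
Mean log2(ChIP/input) in windows of 100 kb (vertical axis) against distance from oriC in kb (horizontal axis) 15 min after release in AB glucose CAA, in LB and in the Dam overproducer in LB, with thin lines for single arrays. The mean over genes within 100 kb was 3.18 in LB (1 array) and 1.46 ± 0.75 in AB glucose CAA (3 arrays).

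Unsynchronised wild-type cells growing slowly in AB acetate were compared with the 4 strains carrying GATC clusters in LB, so medium and genotype differ together. At mioC the level was 4.87 ± 1.49 in acetate (n = 2) and 5.94 ± 1.11, 7.0 ± 0.29, 6.43 ± 0.37 and 5.95 ± 1.01 in the tnaA, hisA, srlA and ter strains. At dnaA it was 3.02 ± 0.98 against 4.73 ± 0.64, 4.38 ± 0.39, 4.81 ± 0.01 and 4.28 ± 0.18, and at rpoB 0.15 ± 0.27 against 1.38 to 1.96. After the dye term none of 4380 genes differed by limma (0 passed, 441 at an unadjusted p under 0.05). Both acetate arrays carry ChIP DNA in Cy5 and all cluster arrays in Cy3. The dye term therefore rests on other groups, and it cannot be told from batch or signal strength. The acetate arrays differed from each other, with r = 0.25 across probes. Replicate 1 was closer to replicate 1 at 5 and at 15 min (r = 0.71 and 0.74), and replicate 2 to the cluster arrays (r from 0.67 to 0.78). Acetate replicate 1 shares a scan with those 5 and 15 min arrays, and their median ChIP signals were alike (89.8, 81.5 and 72.1). Acetate replicate 2 had 854, so this likeness cannot be told apart from batch and signal strength. Without a dye term 47 genes passed, and 1176 in a fit of these 10 arrays alone, where no dye term can be had. The dye-adjusted differences with the smallest adjusted p of their lists were 1.32 at groS, 1.04 at nrdD, -1.44 at dnaC, -1.25 at holD, -1.60 at rpsN, -1.04 at pyrH, 1.46 at atpH and 1.31 at viaA (adjusted p = 0.47 each). At hisA and srlA, where cluster strains hold insertions, they were -2.10 and -0.79 (adjusted p 0.473). The oriC list had a median of 1.17, with 4 higher when adjusted over the list alone (camera adjusted p = 1.1e-08, adjusted p = 0.955 with an estimated correlation). With no dye term this median was -0.34, and the levels at mioC were lower in acetate too, so the direction of the oriC list comes from the dye term, as it does at groS, nrdD and viaA. The rRNA genes had -0.92, or 0.09 under another scaling, and replication genes -0.36 (adjusted p = 0.955 with an estimated correlation for both). All genes had a median of 0.05, and -0.24 with only well measured probes, and the groups share no slide or scan.

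The inserted GATC clusters were asked to show SeqA at their own locus. Probes within 5 kb of srlA, a sorbitol transport gene, averaged 1.78 ± 0.15 in the srlA strain (n = 2) and 0.60 ± 0.19 in the other strains (n = 6), a difference of 1.18. Around hisA, of histidine synthesis, the hisA strain had 0.74 ± 0.03 against -0.24 ± 0.17, a difference of 0.98. At tnaA, the tryptophanase gene, the tnaA strain had 1.72 ± 0.36 against 1.18 ± 0.08, a difference of 0.54. Each gave an exact two-sided permutation p of 0.0357, the smallest that 28 splits of 8 arrays allow. Over the genes alone, tnaA stood at 3.22 ± 0.25 in its strain and 0.34 to 0.38 in the others, hisA at 2.40 ± 0.34 and -0.49 to -0.14, and srlA at 3.41 ± 0.04 and -0.34 to 0.10. After normexp correction the differences were 0.26 at tnaA (exact permutation p = 0.214) and 0.38 at srlA (exact permutation p = 0.0714), and the tnaA difference was 0.29 and 0.79 when 1 of its own arrays was left out (smallest exact p 0.143). Without replicate 1 or 2 of hisA, whose descriptions raise doubts, the hisA difference was 0.96 or 1.00, and without replicate 1 of srlA the srlA difference was 1.07 (exact permutation p = 0.143 each).

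**Figure D4:**
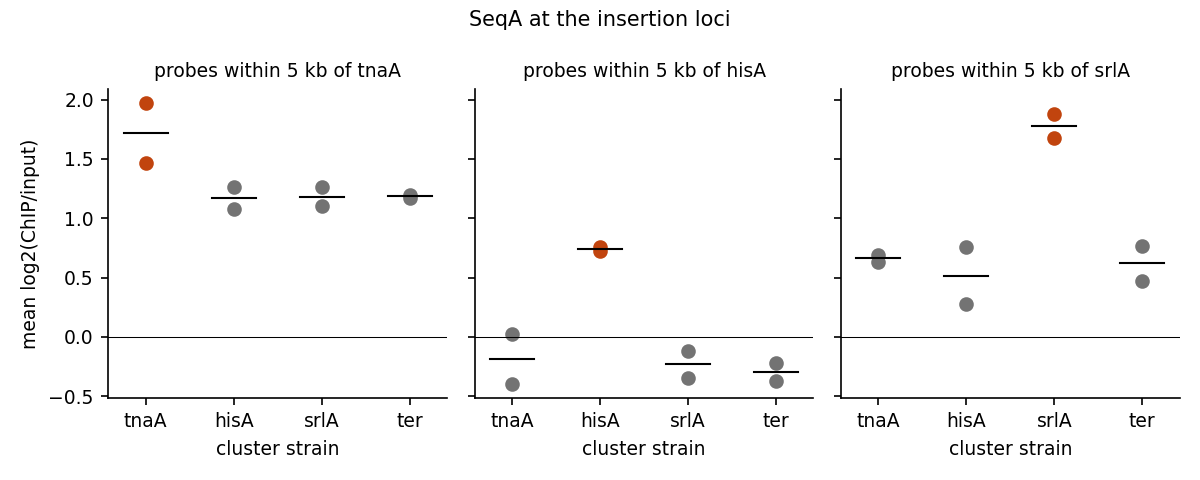
Mean log2(ChIP/input) of probes within 5 kb of tnaA, hisA and srlA (vertical axis) in the 4 cluster strains (horizontal axis), with points for arrays, red for the strain carrying the insertion at that gene, and black lines for means of 2 arrays. The strain with the insertion had the highest mean at its locus, 1.72 at tnaA, 0.74 at hisA and 1.78 at srlA.

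A scan of 928 bins of 5 kb set each strain against the other 3 by limma. In the ter strain the bin 1595001 to 1600000, holding ydeK, lsrK, lsrR and lsrA, was higher by 1.47 (SE 0.22, adjusted p = 0.00158) and its neighbour 1590001 to 1595000, holding hipA, hipB, ydeU and ydeK, by 1.13 (adjusted p = 0.0129). At the persistence gene hipA the level was 1.39 ± 0.08 there and 0.47 to 0.89 elsewhere. In the srlA strain the bins 2825001 to 2830000, with srlE, srlB, srlD, gutM, srlR, gutQ and norR, and 2820001 to 2825000, with recX, recA, ygaD, mltB, srlA and srlE, were higher by 1.20 and 1.07 (adjusted p = 0.0448 both). The bins ranked first for the hisA and tnaA strains were 2090001 to 2095000, at the his operon (1.36, adjusted p = 0.427), and 3885001 to 3890000, with mnmE, tnaA, tnaB and mdtL (1.16, adjusted p = 0.999). The unadjusted p was under 0.05 at 4, 5, 2 and 4 bins for tnaA, hisA, srlA and ter. With slide or scan as a fixed block 0 bins passed for srlA and ter. The ter count was 0 without either ter array and 1 without replicate 2 of srlA, and the srlA count was 2 without replicate 1 of hisA and 0 without any other 1 of the 8 arrays.

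Methylation was measured as DNA surviving DpnI, which cuts methylated GATC, over undigested DNA, on MseI fragments at 0 and 15 min, to see whether new DNA is under-methylated. Fragments with 1 GATC site lay 2.84 and 2.25 below fragments without a site at 15 min (levels -2.84 and -2.25 in replicates 1 and 2) and at -3.03 and -2.24 at 0 min. Fragments with 2 sites lay at -5.46 and -4.40 at 15 min and -5.67 and -4.69 at 0 min. Differences by distance are relative to each array's fragments without a site, not to its overall median. Against the overall median, fragments without a site stood at 1.63 at 15 min and 1.90 at 0 min in replicate 1. In replicate 2 they stood at 1.35 and 1.37. Differences on the overall-median scale would therefore be smaller in replicate 1. Relative to fragments without a site, those with 1 or 2 sites 250 to 500 kb from oriC were higher at 15 min. The median difference was 0.55 in replicate 1 (quartiles 0.24 and 0.94, 613 fragments) and 0.11 in replicate 2 (quartiles -0.08 and 0.31, 612 fragments). From 500 to 750 kb these medians were 0.31 and 0.06, from 100 to 250 kb 0.27 and 0.06, within 100 kb 0.17 and 0.04, and from 1000 to 1500 kb 0.03 and 0.01. Fragments without a site gave -0.01 and -0.07 from 250 to 500 kb. Replicate 1 was not crosslinked and replicate 2 was, all 4 arrays lie on 1 slide, and no test was made of these medians.

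Over genes and intergenic stretches none of 5518 passed by limma (0 calls, 91 at an unadjusted p under 0.05, smallest adjusted p 1.00). With the replicate number, which marks crosslinking, as a replicate block, 24 were higher and 39 lower. All of these had the same SE, 0.23, so the calls rank the size of the difference and use no feature's own spread. They include purE (-1.07) and the stretch between der and bamB (0.99), whose fragments hold 0 GATC sites and so no site for DpnI. These calls therefore do not establish changes in methylation. The lower side was led by hflK (-2.26) and hchA (-1.84), 477 and 1889 kb from oriC. The higher side was led by ybhR (1.52) and the stretch between frdA and poxA (1.41), 1541 and 457 kb from oriC. Without replicate 1 or 2 at 15 min 9 or 8 passed. The band from 250 to 500 kb had a median of -0.02 and a mean of 0.01, above other features by camera (camera adjusted p = 2.2e-05, adjusted p = 0.999 with an estimated correlation), the band from 500 to 750 kb -0.05 and ribosomal protein genes 0.04 (adjusted p = 0.999 with an estimated correlation). The values of this paragraph are centred on each array's overall median and average fragments with and without sites. They are thus not on the scale of the medians by site number.

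**Figure D5:**
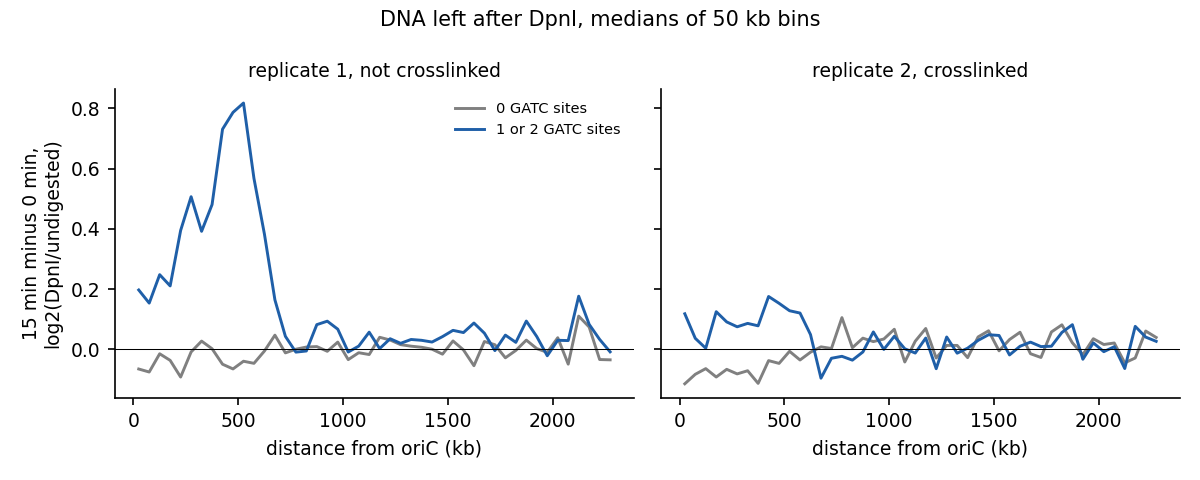
Median difference in log2(DpnI/undigested) between 15 and 0 min (vertical axis) in bins of 50 kb against distance from oriC in kb (horizontal axis), for fragments with 1 or 2 GATC sites in blue and without a site in grey, in replicate 1 and replicate 2. Differences are relative to each array's fragments without a site. Between 250 and 500 kb the fragments with sites had medians of 0.55 and 0.11 and those without -0.01 and -0.07.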

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

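All tests in this part, and the genes it names, were chosen after the results were seen.

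On the 18 arrays of the dnaC2 strain, 447 of 495 probes between 1389020 and 1444645 (55.6 kb) had next to no input DNA. All probes of 51 genes from ycjZ to ydbL lacked input, among them fnr, a regulator of anaerobic growth, recE, recT and trkG of a cryptic prophage. The median log2 input there was -9.55 to -6.46 on the dnaC2 arrays and -0.51 to -0.02 on the 10 arrays of other strains, so the nearest arrays of both kinds lay 5.95 apart. Probes that fail to hybridise are argued against by the lowest value in the other strains, -0.51. A deletion in the dnaC2 strain may account for it, since undigested DNA of that strain on the methylation arrays, a separate probe design, was no higher than -6.07 in the stretch, against -0.24 to -0.15 within 50 kb of it.

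A step in input DNA was seen on the 5 time-course arrays that share a slide with a 0 min array, data outside the SeqA ratio. Input near oriC exceeded input farther out by 0.33 and 0.40 in replicates 1 and 2 at 5 min, 0.38 at 15 min, 0.79 at 35 min and 0.36 at 50 min (log2, against the 0 min array of the slide). The steps lay at 150, 125, 550, 1350 and 950 kb and the SeqA edges of the same arrays at 113, 75, 575, 1475 and 1075 kb. Less input DNA inside the edge, which would raise the ratio by itself, is argued against by the lowest step, 0.33. The largest distance between step and edge was 125 kb. From 5 to 35 min this goes with an edge at the end of the replicated part, a hypothesis formed on these arrays. At 50 min both step and edge lay nearer oriC than at 35 min. There they cannot be read as the farthest point replicated, and the cause was not tested.

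The rRNA genes stood above their neighbours in the 4 cluster strains, by a median of 0.83 and a range of 0.32 to 2.44 over the 8 arrays, with 12 genes measured and copies that are near identical. GATC density is argued against, since rRNA genes had 0.60 fewer sites per kb than their neighbours (difference -0.60). Against the slide as the whole cause stands 1 pair of cluster arrays on one slide that differed by 1.31, replicate 1 of hisA at 0.59 and replicate 1 of srlA at 1.90. The descriptions of both arrays raise doubts. The other pair on one slide, replicate 2 of tnaA and of srlA, stood at 0.32 and 0.65, so the slide is not settled. Recovery of DNA that needs no hemimethylated GATC may contribute and cannot be told apart, because the excess at 0 min reached 0.42, within the range of the cluster arrays. The media differ too, and a biological explanation was not tested.

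Input DNA of the dam gene exceeded that of its neighbours by 0.49 and 0.79 on the 2 arrays of the Dam overproducer, against -0.94 to 0.02 on the other 26 arrays and -0.12 on the parent's.

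The brightest of 3 probes for plasmid sequence on the methylation design had an undigested signal from 1223 to 1546 on the 4 arrays, where the genome's medians were 19057 to 30506. The other 2 had 76 to 114 and 41 to 112, mostly not well above background.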

How the results depend on the processing

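Array weights, slide or scan as a fixed block, probes without input, leaving out dim arrays and the methylation alternatives on GATC-free fragments were tests chosen after the results were seen, and the rest were planned. Of 323 alternative values over 18 comparisons, 204 were alike. For counts this means a total, higher and lower together, within 1.5 times, with direction not compared. At the cluster loci it means the same direction and the same side of the threshold. Of 1620 values for 87 named genes 1206 kept their call, 414 lost it and 0 reversed. These genes were picked on the same data for size and for arrays that do not overlap. A reversal was therefore unlikely from the start, and its absence is no independent support. Where no reason is given below, the cause was not tested. Dim ChIP signal at 0 min and in replicate 2 at 5 min limits the comparisons with 0 min.

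Counts of genes moved as follows. For 5 against 0 min (47) it was 15 with no dye term, 0 after normexp, 129 with scaling to one median absolute deviation, 16 with well measured probes, 95 with the value table, 0 in a fit of the groups compared, 3 without described arrays, 30 with slide fixed, 17 with array weights and 1 to 130 leaving out an array. For 15 against 0 min (313) it was 612 with no dye term, 45 after normexp, 200 with well measured probes, 179 with the replicate block, 79 without described arrays, 147 with slide fixed and 124 to 573 leaving out an array. For 16 against 15 min (0) it was 1 with no dye term, 2 with medians per gene, 52 with array weights and 0 to 1 leaving out an array. For 17 against 15 min (95) it was 1 after normexp, 31 with scaling, 36 with the replicate block, 0 in a fit of the groups compared, 56 without described arrays, 9 with slide fixed, 1 with array weights and 1 to 206 leaving out an array. For 35 against 15 min (936) it was 553 after normexp, 616 with scaling, 515 with well measured probes, 614 with the replicate block, 158 with slide fixed, 225 with array weights and 43 to 2034 leaving out an array. For 50 against 35 min (726) it was 0 after normexp, 195 with well measured probes, 15 in a fit of the groups compared, 403 without described arrays, 435 with slide fixed, 0 with array weights and 0 to 1418 leaving out an array.

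For Dam overproduction (0) it was 7 with scaling, 123 with well measured probes, 106 with medians per gene, 124 in a fit of the groups compared, 22 with slide and 24 with scan fixed, 120 without dim arrays, 604 with array weights and 0 to 1 leaving out an array. For LB against AB glucose CAA (392) it was 0 with scaling, 157 with the replicate block, 764 in a fit of the groups compared, 0 without described arrays, 2 with slide and 7 with scan fixed, 879 with array weights and 221 to 398 leaving out an array. For AB acetate (0) it was 47 with no dye term and 1176 in a fit of the groups compared, where the dye term could not be fitted. For methylation (0) it was 63 with the replicate block and 0 to 9 leaving out an array, and 0 when centred on fragments without GATC or limited to fragments with GATC, with or without the block.

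Bins for tnaA (0) were 1 in a fit of the groups compared and 1 with array weights. Bins for srlA (2) were 1 with well measured probes, 1 with medians, 0 to 2 leaving out an array, and 0 with no dye term, normexp, the value table, the replicate block, a fit of the groups compared, slide as a random or fixed block, scan as a fixed block and without dim arrays. Bins for ter (2) were 0 with well measured probes, with slide or scan fixed, and 0 to 2 leaving out an array. At the loci, tnaA (0.54) was 0.26 after normexp, 0.53 with scaling, 0.56 without described arrays and 0.29 to 0.79 leaving out an array. For hisA (0.98) the range was 0.95 to 1.03 leaving out an array, and srlA (1.18) was 0.38 after normexp, 1.03 without described arrays and 1.07 to 1.28 leaving out an array. Without 1 of the strain's own arrays the smallest possible exact p is 0.143, and without 1 of another strain's each locus kept the smallest possible, 0.0476. Of the gene lists, 93 passed at the preset and 5 with an estimated correlation.

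Among lists and bands that passed by fry, directions turned in these cases. Some lists that did not pass turned too, several of them given in the comparisons. The replication list at 15 against 0 min (0.34) was -0.20 after normexp and -0.016 to 0.38 leaving out an array, and the band beyond 1500 kb at 35 against 15 min (-0.67) was -1.27 to 0.067 leaving out an array. In the Dam comparison, scaling gave 0.61 for the dnaA operon region, 0.61 for the oriC list and 0.47 for 250 to 500 kb. The nucleotide synthesis list in LB (0.29) was -0.044 after normexp and -0.17 with well measured probes.

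Equal replicate numbers on the SeqA arrays share a number and, in part, a slide, which is tested as its own block, with correlations of deviations of 0.24 for 5 and 0 min, 0.20 for 15 and 0, -0.43 for 16 and 15, -0.91 for 17 and 15, 0.66 for 35 and 15 and 0.40 for 50 and 35. The replicate block changed no count by more than 1.5 times beyond those given. Not run were the described-array alternative for AB acetate, hisA and the bins, leaving out the LB array, a slide block for methylation, a slide or scan block for AB acetate, the comparisons with 0 min without dim arrays, and GATC-density classes.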

Other observations

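The test below was chosen after the values were seen. In unsynchronised cells, genes 500 to 750 kb from oriC had mean levels of 0.49 to 0.54 in the 4 cluster strains and 0.13 in AB acetate, and genes within 100 kb had 0.17 to 0.29 and 0.32 ± 0.01 (n = 2 arrays per group). These levels are not adjusted for dye, and the groups differ in dye orientation.

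Levels of SeqA near oriC varied between neighbouring stretches. SeqA was set against GATC sites per kb over 94 bins of 5 kb within 250 kb of oriC. Its level followed that number on each of the 13 time-course arrays from 5 min on. Across bins within an array r was 0.59 to 0.82 and the rank correlation 0.46 to 0.78. On the arrays at 0 min the highest r was -0.15 and the highest rank correlation 0.06. At 5 min the mean SeqA edge was at 93.8 kb, so the bins lie on both sides of it. Neighbouring bins are not independent, so no p is given. Beyond the edge, from 1000 to 1500 kb, r was 0.64 on the LB array and 0.47 and 0.11 on replicates 1 and 2 at 5 min. It was 0.31, 0.05 and 0.07 on replicates 1, 2 and 3 at 15 min. GATC density may set part of the level, a hypothesis that these values do not tie to replicated DNA.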
